A study of Mus musculus with 7 samples.

How the data were processed

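Islets were isolated from female NOD/ShiLtJ mice by collagenase digestion, density gradient and hand picking and kept in culture overnight, per the labels. RNA was extracted with a miRNeasy kit and pretreated with a kit that repairs the ends of tRNA fragments and removes base modifications, and libraries were made with a QIAseq miRNA kit, per the labels' protocols. Such pretreatment lets fragments be ligated and read that would otherwise be missed. Bowtie 1, a short-read aligner, and the build GRCm38.p6 are named without settings, per the submitters' processing notes. The counting tool, tRNA annotation, filters, adapter handling and use of molecular identifiers are not given in the sources used here, so intervals and limits cover counting error only.

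A single table gave, for each fragment sequence and library, the read count the authors deposited and a pair of RPM values (reads relative to a library constant) that the authors deposited under headers reading TPM. Count divided by RPM was the same for every fragment of a library, so neither has a length correction, and each rests on a constant per library. What the constants count is not given in the sources used here. The first ran from 6909421 to 17062497 and the second from 670335 to 2049251, and the table's counts were 21.1% to 33.7% of the second. The second was 4.59% to 17.7% of the first, lowest in 4-week replicate 3 (4.59%) and 8-week replicate 1 (5.47%). The table holds 51 to 70 nt fragments with a tRNA source, so shorter fragments and other small RNAs were not analysed here. Of 6456 fragments, 3291 matched more than 1 tRNA gene and 2810 were seen in 1 library.

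Counts as deposited were tested with edgeR 4.0.16 (quasi-likelihood F-test, robust, TMM scaling, filterByExpr) in R 4.3.3, on 740 fragments holding at least 97.0% of each library's counts, with Benjamini-Hochberg adjustment and a threshold of 0.05. TMM factors ran from 0.588 to 1.59, and the biological coefficient of variation was 0.487. The same test was run on counts summed per source tRNA and type (129 of 207 sums passed the filter). The 25 sets with at least 5 tested members (fragment types, amino acids, genome of origin) were tested on log2 CPM with a prior count of 2, with camera (preset correlation 0.01, and estimated) and fry of limma 3.58.1. Shares of counts were compared by an exact two-sided permutation test over all 35 splits, adjusted within each family. Centred log2 levels of a set are means over its members. The smallest p-value of that test is 0.0286. Groups came from the age labels and replicates were numbered in accession order, which pairs nothing.

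The groups, tests, sets, first list of alternatives and rule for named fragments were fixed before the data were examined. The rule named the passing fragments whose libraries do not overlap between ages (up to 10 per direction, 1 per source and type), the 5 with the smallest p in a direction where none pass, the 10 most abundant, each set, and passing sums. Alternatives were DESeq2 1.42.0 (size factors and Wald test), total counts alone, other filters, limma-voom, no robust estimation, other thresholds, nuclear sources alone, and each library left out. Either constant as library size, the removal of fragments seen in 8-week replicate 4 alone, the removal of 8-week replicates 1 and 4 together, fry and medians under other scalings, and fry and the DESeq2 Wald test of sums with libraries left out were added after seeing the data. Scaling moved the median log2 fold change of all fragments from 0.10 to 0.17 (DESeq2), −0.36 (total counts), 0.05 (first constant) and −0.44 (second constant), so changes are relative to these.

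The tests were tested on simulated data before use. For 740 fragments with 200 changed, 1.23% of unchanged fragments were called, and 13.5%, 72.0% and 98.3% of those changed by 1, 2 and 3 on the log2 scale. For 129 sums with 40 changed, the shares were 0.696%, and 14.8%, 81.3% and 98.5%. No pair of libraries of an age agreed within sampling noise (chi-square per degree of freedom 24.5 to 163). Mitochondrial tRNA genes were located in the GENCODE M21 annotation of GRCm38 from their fragments' sequences. For nuclear tRNA genes the chromosome is given as in the table, and start and end are not given here. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.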

Results

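Fragments of transfer RNA (tRNA) were counted by small RNA sequencing in pancreatic islets of female NOD/ShiLtJ mice, a strain that develops autoimmune diabetes spontaneously. Islets of 4-week-old mice (3 libraries), which still look and work normally, were compared with islets of 8-week-old mice (4 libraries), an age at which immune cells have begun to enter the islets and diabetes has not appeared. The series asks whether tRNA fragments take part in the first phases of the disease. The labels do not say whether the libraries of an age came from separate animals or pools, so every p-value measures the spread between these samples. The table held 6456 fragment sequences of 51 to 70 nt, of which 4728 came from nuclear tRNAs, 1689 from mitochondrial tRNAs and 39 from both. Total counts over these fragments were 265331, 235642 and 198330 at 4 weeks and 245905, 431743, 270109 and 411137 at 8 weeks.

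Each fragment is named by its source tRNA, amino acid and anticodon, its type, and its first and last position along the tRNA. A 5-tRF starts at the 5' end of the tRNA, a 3-tRF ends at or near the 3' end, and an i-tRF is internal. A 3-tRH starts near the anticodon and ends at or near the 3' end. These 4 types held 1267, 2558, 2551 and 80 fragments, and 6406 of the 6456 spanned the whole anticodon. Of the 3-tRFs 1533 ended in CCA, the end of a mature tRNA, and of the 3-tRHs 56. A few fragments dominated every library, the 10 most abundant taking 42.5% to 63.9% of a library's counts. Libraries of the same age were about as alike as libraries of different ages. The correlation across fragments of log2 CPM (counts scaled to a common library size) had a median of 0.904 over 9 same-age pairs and 0.890 over 12 different-age pairs, fragments not being independent replicates.

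A fragment of a leucine tRNA fell between 4 and 8 weeks, and it was the 1 fragment of 740 tested that passed. This 5-tRF of tRNA-Leu-TAA-2, positions 1 to 64, dropped from a TMM-scaled CPM of 229 ± 32.3 (SD, n = 3) to 39.4 ± 8.05 (SD, n = 4), a log2 fold change of −2.54 (SE 0.41) with an adjusted p of 0.0431 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 4 libraries at 8 weeks lay below all 3 at 4 weeks. Its tRNA is among 12 that had 3' fragments ending in CC but none ending in CCA in 6 libraries (52 and 0 reads), and 348 CCA-ended reads in 8-week replicate 4. Its sequence was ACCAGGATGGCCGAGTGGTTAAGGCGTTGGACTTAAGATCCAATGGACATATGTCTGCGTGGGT, it included the anticodon at positions 34 to 36 of a tRNA of 87 nt, and it matched 1 nuclear tRNA gene, on chromosome 10. The call ended when any 1 of the 7 libraries was left out, at adjusted p values of 0.0605 to 0.305 in edgeR, while the log2 fold change stayed between −2.69 and −2.40. Of the 18 alternatives that changed its fit, 5 passed and 13 did not (adjusted p 0.000144 to 0.996 in edgeR, DESeq2 or limma-voom).

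The next fragments in order of p were also lower at 8 weeks and did not pass in edgeR. They were singled out after their values were seen. A 5-tRF of tRNA-Leu-CAG-1 and tRNA-Leu-CAG-2, positions 1 to 54, had 71.0 ± 2.06 CPM at 4 weeks (SD, n = 3) and 5.54 ± 4.501 at 8 weeks (SD, n = 4), with an adjusted p of 0.0587 in edgeR. It matched 8 genes on chromosomes 1, 8 and 13, so its counts cannot be assigned to a single gene. Its 8-week mean lay below the level that a count of 0 allows there, 6.95 to 12.2 CPM before TMM scaling. The size of its drop is therefore uncertain. Overlapping 3-tRFs of tRNA-Asn-GTT-3 starting at positions 22 and 23, which match 9 genes on chromosomes 1, 2, 3, 5, 10 and 11, had log2 fold changes of −1.69 and −1.59 and adjusted p values of 0.139 in edgeR. The DESeq2 Wald test called 4 fragments, which were the Leu-TAA-2 fragment, the Leu-CAG fragment and these Asn-GTT-3 fragments, all lower, and limma-voom called 1.

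No fragment passed as higher at 8 weeks in edgeR, DESeq2 or limma-voom, against 30 higher and 46 lower at an unadjusted p under 0.05 in edgeR. The 5 with the smallest p came from mitochondrial glutamine, glutamate and histidine tRNAs and from nuclear lysine and threonine tRNAs, each with an adjusted p of 0.449 in edgeR. A 5-tRF of mitochondrial Glu-TTC, positions 1 to 51, had 148 ± 23.3 CPM at 4 weeks (SD, n = 3) and 342 ± 119 at 8 weeks (SD, n = 4). A 3-tRF of tRNA-Lys-TTT-1, positions 16 to 76, had 303 ± 90.6 and 652 ± 125. The log2 fold changes were 1.97 for mt-Gln-TTG 5-tRF 1-64, 1.40 for mt-His-GTG 5-tRF 0-52 and 1.27 for tRNA-Thr-TGT-2/3 3-tRF 12-76. The mitochondrial sources are the genes mt-Te (chromosome M, 14071 to 14139, minus strand), mt-Tq (3772 to 3842, minus strand) and mt-Th (11546 to 11612, plus strand) in GRCm38. Libraries of the 2 ages did not overlap for 86 of the 740 fragments (11.6%), 22 above and 64 below at 8 weeks. Random splits average 5.71%, but overlapping fragments move together and the spread over single splits was not counted. Nothing follows for chance from this share. In a simulation, 200 of these 740 fragments were changed and each fragment was drawn independently. There, 13.5%, 72.0% and 98.3% of changes of 1, 2 and 3 on the log2 scale were called. With fewer changed fragments the adjustment is stricter, and the real fragments overlap. These shares therefore do not give the share of changes that would be called here.

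**Figure D1:**
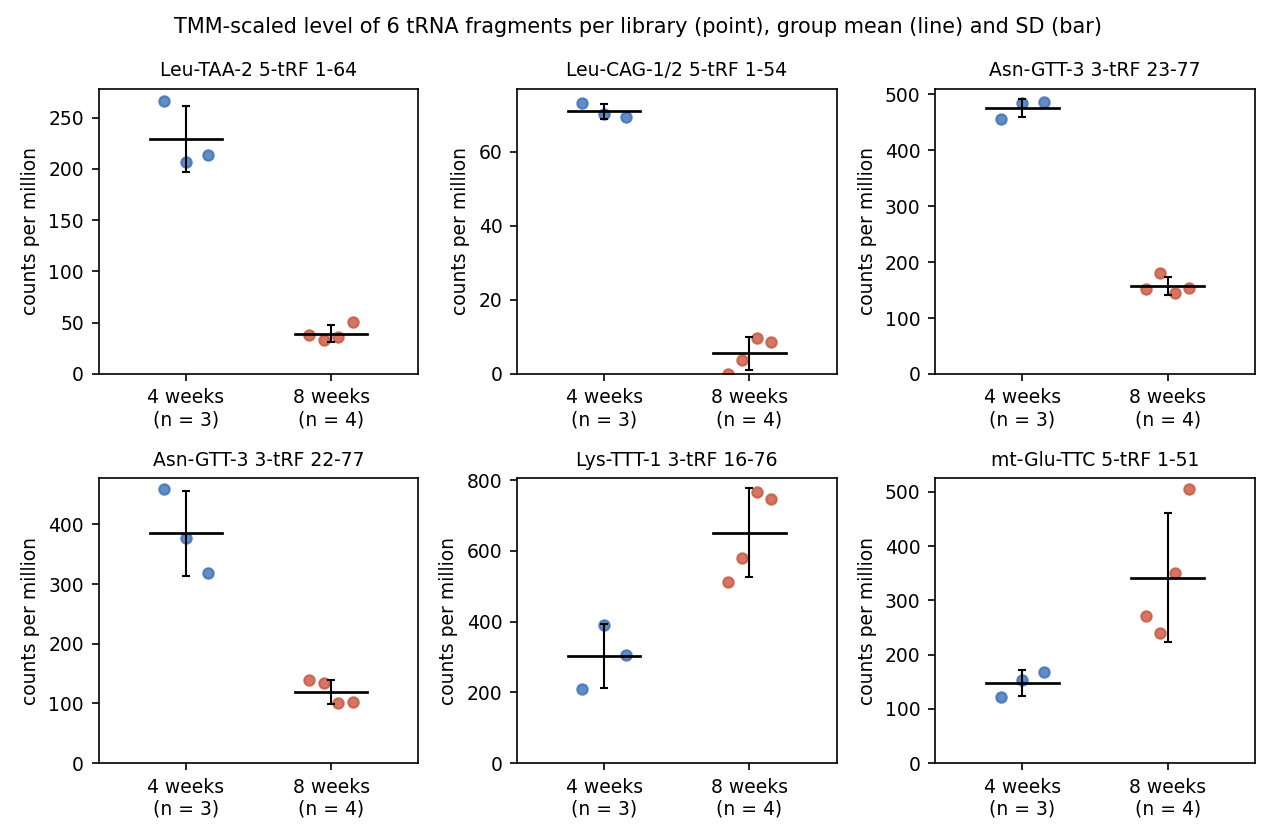
Level of 6 tRNA fragments in TMM-scaled CPM (linear axes from 0), with 1 point per library at 4 weeks (n = 3) and 8 weeks (n = 4), group means as lines and SD as bars. The Leu-TAA-2 fragment passed the test (229 to 39.4 CPM), and the other 5 fragments did not.

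The most abundant fragments did not pass in either direction. Among the 10, 6 were nested 3-tRFs of tRNA-His-GTG-2, which carries histidine and has 8 matching genes on chromosomes 2, 3 and 4, and another pair came from tRNA-Glu-CTC-1. The His-GTG-2 3-tRF 13-75 alone had 77030 ± 45074 CPM at 4 weeks (SD, n = 3) and 118158 at 8 weeks, with a log2 fold change of 0.62 (SE 0.61), or 0.07 with total counts alone. The Glu-CTC-1 3-tRF 12-75 had 65627 and 118787, a log2 fold change of 0.86 (SE 0.50). Mitochondrial 5-tRFs made up the remaining pair. The mt-His-GTG 5-tRF 0-51 starts at the extra G that histidine tRNAs carry ahead of position 1, and it had 19258 ± 9818 (SD, n = 3) and 90479 CPM. The mt-Gly-TCC 5-tRF 1-51, from the gene mt-Tg (chromosome M, 9391 to 9458, plus strand), had 11184 ± 865 and 40148. Both 8-week means rested on 8-week replicate 1, at 270102 and 128222 CPM, and without it the log2 fold change of the mt-Gly-TCC fragment was −0.05. The direction of the His-GTG-2 12-75 and 8-75 and Glu-CTC-1 13-75 fragments turned with total counts alone or the second deposited constant as library size.

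Counts summed per source tRNA and fragment type gave 129 tested sums, and none passed in edgeR. The lowest adjusted p, 0.139, belonged to the leucine Leu-TAA 5-tRFs, at 392 ± 85.9 CPM at 4 weeks (SD, n = 3) and 91.6 ± 51.03 at 8 weeks (SD, n = 4), a log2 fold change of −2.09. The 3-tRFs of Arg-TCG had a log2 fold change of −1.01 and the 3-tRFs of Lys-TTT one of 1.07, with adjusted p values of 0.242 and 0.285 in edgeR. At an unadjusted p under 0.05 there were 10 higher and 11 lower sums. The DESeq2 Wald test called 7, which were higher for mt-His-GTG 5-tRFs, Lys-TTT 3-tRFs and Lys-TTT i-tRFs and lower for Arg-TCG 3-tRFs and the 5-tRFs of Leu-CAG, Leu-TAA and Leu-TAG, and limma-voom called 0. The mt-His-GTG 5-tRFs stood at 284639 CPM in 8-week replicate 1 and at 31743, 61670 and 71950 in the other 8-week libraries, and without that library the log2 fold change was 1.02 with an adjusted p of 0.0840 in DESeq2. That call also ended without 4-week replicate 1, 2 or 3 (adjusted p of 0.289, 0.0926 and 0.0964 in DESeq2). There the log2 fold changes were 1.79, 2.07 and 2.33, against 2.08 with all libraries. With 1 library left out the DESeq2 Wald test called 1 to 17 sums, the fewest (1) without 4-week replicate 1, 2 or 3 and the most (17) without 8-week replicate 3, and the Leu-TAA 5-tRFs were called each time. That sum includes the Leu-TAA-2 fragment called above, so it is not a separate result. The DESeq2 test of sums was not run on other splits of the libraries. Without 8-week replicate 3 or 8-week replicate 4, the Leu-TAA 5-tRFs passed in edgeR, as 1 called sum in each case.

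Fragments of leucine and asparagine tRNAs were lower at 8 weeks as groups, and those of histidine and lysine tRNAs were higher, relative to the other fragments. On the log2 CPM scale of the set tests, all 22 leucine fragments were lower, with a median log2 difference of −1.10, and 15 of 17 asparagine fragments were lower, with a median of −0.96. Of 108 histidine fragments 92 were higher, with a median of 0.51, and of 32 lysine fragments 25 were higher, with a median of 0.50. By edgeR's fitted values, 21 leucine and 14 asparagine fragments were lower, and 86 histidine and 29 lysine fragments higher. The higher counts hang on the scaling. With total counts alone 62 histidine and 18 lysine fragments were higher, and with the second constant 57 and 18. They were 93 and 30 with DESeq2 size factors and 85 and 29 with the first constant. With total counts or the second constant, 22 leucine and 16 asparagine fragments were lower. The mean log2 level of the leucine set per library was 0.61 ± 0.10 at 4 weeks (SD, n = 3) and −0.46 ± 0.41 at 8 weeks (SD, n = 4), that of the asparagine set 0.47 ± 0.08 and −0.35 ± 0.32, and that of the histidine set −0.29 ± 0.16 and 0.22 ± 0.11. Limma's camera test with a preset correlation of 0.01 gave adjusted p values of 2.87e-09 for leucine, 5.19e-07 for asparagine, 1.74e-07 for histidine and 0.000261 for lysine. The calls were lost with an estimated correlation, at adjusted p = 0.178 for leucine and asparagine, 0.0523 for histidine and 0.203 for lysine with an estimated correlation in limma's camera. That correlation was 0.196 for leucine, 0.137 for asparagine, 0.00932 for histidine and 0.0773 for lysine. Within the lists, 2 leucine and 7 asparagine fragments passed as lower when adjusted over the list alone, and 0 histidine and 0 lysine fragments, against 1 leucine fragment over all 740. Each list was adjusted on its own, here and below, with no correction across lists. The asparagine fragments with the smallest p, starting at positions 18, 19, 22 and 23, are overlapping 3-tRFs of tRNA-Asn-GTT-3 and not independent. Over all 740, the lowest asparagine adjusted p was 0.139 in edgeR.

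Limma's fry, which tests whether the members of a set move on balance one way and does not compare the set with others, called 6 of the 25 sets. These were leucine, asparagine and histidine (adjusted p = 0.0420 each), and proline, lysine and initiator methionine (adjusted p = 0.0478 each). Initiator methionine tRNA starts protein synthesis. Its 9 fragments had a median of −0.86 (−0.53 without 4-week replicate 1), and 2 passed as lower when adjusted over the list alone. The 47 proline fragments had a median of −0.41, with 0 passing over the list alone. With any 1 library left out fry called 0 sets, except that histidine was called without 8-week replicate 2 (adjusted p = 0.0308), and it called 0 without 8-week replicates 1 and 4 together. With total counts alone or the first deposited constant as library size fry called 0 sets, and with the second constant it called 8, all lower. The lysine median was −0.01 under that second constant, and the histidine median stayed at 0.01 or above.

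Limma's camera with the preset correlation called 12 of the 25 sets. Splitting the 7 libraries into 3 and 4 in the other ways gave a median of 10. The called sets beyond leucine, asparagine, histidine and lysine included fragments of mitochondrial tRNAs, glutamate and alanine, which were higher. Those of nuclear tRNAs, proline, tryptophan, methionine and initiator methionine were lower. The mitochondrial and nuclear sets together are all the tested fragments, so in a test against the rest their calls are the same result. All 19 alanine fragments came from mt-Ala-TGC, so that set lies within the mitochondrial one. The 227 mitochondrial fragments had a median of 0.27, the 88 glutamate fragments 0.28, the 19 alanine fragments 0.50, the 513 nuclear fragments −0.10, the 25 methionine fragments −0.41 and the 5 tryptophan fragments −1.14. With an estimated correlation limma's camera called 0 sets, at adjusted p = 0.708 for mitochondrial, glutamate and alanine, 0.178 for proline and initiator methionine, 0.203 for methionine and nuclear, and 0.336 for tryptophan. Adjusted over the list alone, 2 nuclear fragments passed as lower and 0 of the mitochondrial, glutamate, alanine, methionine and tryptophan ones. The mitochondrial median was −0.12 without 4-week replicate 3 and −0.0022 without 8-week replicate 3, and neither was called. Without those libraries the nuclear and alanine calls ended too, at −0.18 and 0.17 without 4-week replicate 3 and at −0.05 and 0.39 without 8-week replicate 3. Glutamate was not called without 4-week replicate 2 (0.21) or 8-week replicate 4 (0.14), nor with total counts alone (adjusted p = 0.0583 in limma's camera). Initiator methionine was not called without 4-week replicate 3 (−0.73). Still called, the methionine median was −0.16, −0.69 and −0.62 without 4-week replicate 1, 4-week replicate 2 and 8-week replicate 4. Without 4-week replicate 2 the alanine, nuclear and mitochondrial medians were 0.77, −0.16 and 0.43, and without 8-week replicate 4 the alanine and mitochondrial ones were 0.76 and 0.50. The mitochondrial median was also 0.41 without 4-week replicate 1 and 0.40 without 8-week replicate 1. The fitted medians of the mitochondrial and glutamate fragments, 0.39 and 0.36, turned to −0.05 and −0.15 with total counts alone and to −0.14 and −0.18 with the second constant, and that of the nuclear fragments, −0.06, to 0.01 with DESeq2 size factors. The alanine median was −0.0023 on the log2 CPM scale with the second deposited constant. After a linear trend on GC content and length per library was removed, the medians were 0.08 for mitochondrial, 0.26 for alanine, 0.37 for glutamate and −0.0068 for nuclear fragments.

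The fragment types did not differ as sets, at preset-correlation adjusted p values in limma's camera of 0.227 for 3-tRHs and i-tRFs, 0.473 for 5-tRFs and 0.872 for 3-tRFs. The remaining amino acids (serine, threonine, glutamine, glycine, arginine, isoleucine, cysteine, valine and aspartate) were not called either, the lowest adjusted p being 0.219 for serine in limma's camera. Adjusted over the list alone, 2 of the 240 5-tRFs passed as lower and no member of these other sets did. For the 3-tRFs the median of 0.02 and mean of 0.01 were positive while the test pointed lower, and for aspartate the median was −0.02 and the mean 0.02. Of the 25 sets, 2 (histidine and lysine) lay above and 6 (asparagine, leucine, proline, methionine, initiator methionine and tryptophan) below without overlap of the ages. Random splits average 5.71%, but the sets share fragments and the spread over single splits was not counted, so nothing follows for chance.

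**Figure D2:**
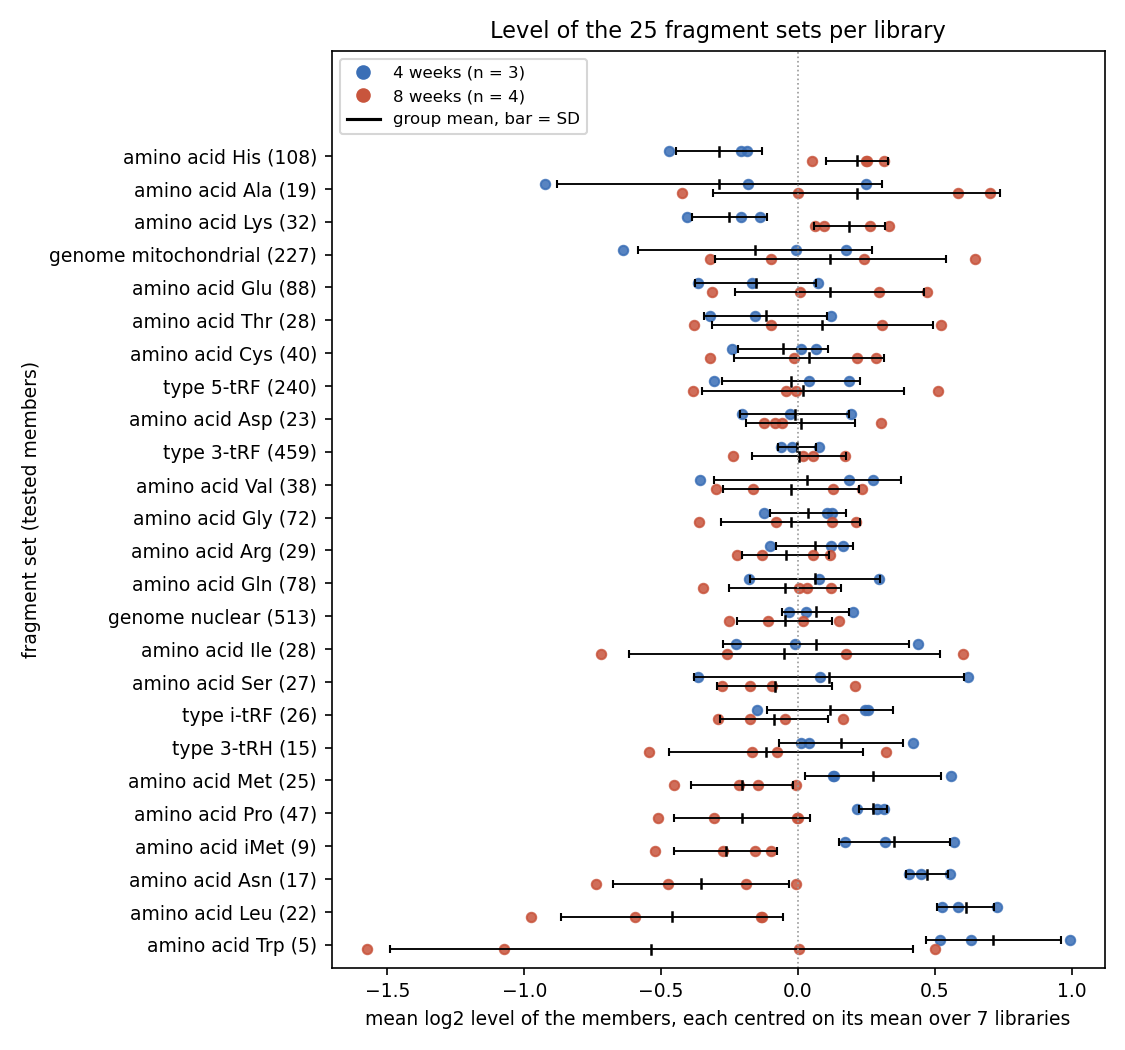
Mean log2 level of the tested members of each of 25 fragment sets, each member centred on its mean over the 7 libraries, with 1 point per library at 4 weeks (n = 3) and 8 weeks (n = 4), group means as ticks and SD as bars. The leucine set lies at 0.61 at 4 weeks and −0.46 at 8 weeks and the histidine set at −0.29 and 0.22, under the main scaling.

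As shares of a library's counts, asparagine, leucine and proline fragments were a smaller part at 8 weeks without passing the correction. Asparagine fragments made up 1.25% ± 0.11 at 4 weeks (SD, n = 3) and 0.615% ± 0.12 at 8 weeks (SD, n = 4), leucine fragments 0.902% ± 0.17 and 0.476% ± 0.13, and proline fragments 2.36% ± 0.56 and 1.35% ± 0.32. Each had an exact two-sided permutation p of 0.0286, the smallest that the 35 splits allow, and an adjusted p of 0.210 over 22 amino acid classes, with all 4 libraries at 8 weeks below all 3 at 4 weeks. Histidine fragments were the largest class, at 49.4% and 55.3%, followed by glutamate at 19.0% and 20.5%. The 3-tRFs made up 85.1% ± 3.03 and 80.4% ± 11.2, the 5-tRFs 13.2% ± 2.55 and 18.4% ± 11.1, and mitochondrial fragments 13.6% ± 3.03 and 19.8% ± 11.5. The 8-week replicate 1 held 35.3% mitochondrial fragments, and without it the difference in the mitochondrial share fell from 6.14 to 0.960 percentage points, that in the 5-tRF share was −0.0624 and that in the 3-tRF share 0.598. Without 8-week replicate 4 the mitochondrial difference was 9.76 points. Mean fragment length was 60.2 ± 0.24 nt and 60.1 ± 1.21 nt, a difference that turned to 0.451 nt without 8-week replicate 1 and to 0.197 nt without the 10 most abundant fragments. With nuclear sources alone as denominator it turned to 0.571 nt and passed (exact two-sided permutation, adjusted p = 0.0286), and the 3-tRF and 5-tRF differences turned to 1.97 and −1.54 points. Mean length is the only class of its family, so this p is not corrected and is the smallest that the 35 splits allow.

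**Figure D3:**
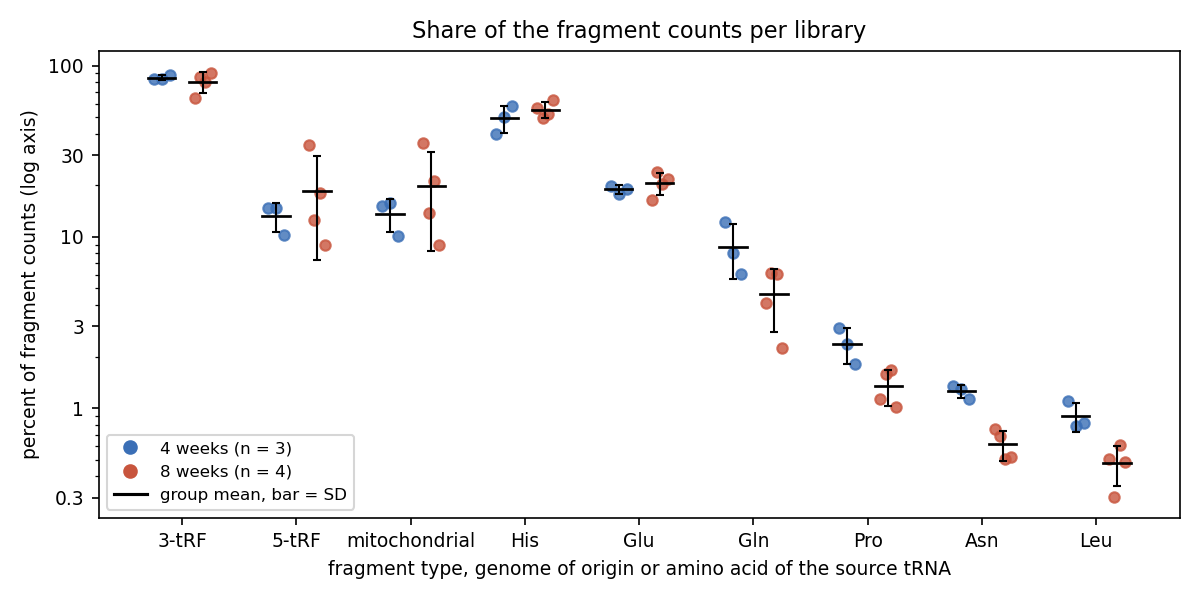
Percent of a library's fragment counts (log axis) by fragment type, mitochondrial origin or amino acid of the source tRNA, with 1 point per library at 4 weeks (n = 3) and 8 weeks (n = 4), group means as lines and SD as bars. The asparagine share was 1.25% at 4 weeks and 0.615% at 8 weeks, and the highest mitochondrial share, 35.3%, was that of 8-week replicate 1.

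Mature tRNAs end in CCA, added after transcription, and 1 library differed from the rest in which CCA-ended fragments it held. In 8-week replicate 4, 177 fragments with at least 5 reads were at 0 in the other 6 libraries, together 6853 reads or 1.67% of that library, and 176 of them ended in CCA. A count of 0 allows up to 6.95 to 15.1 CPM, depending on the library, by counting error only, and 5 reads in 8-week replicate 4 are 12.2 CPM. Fragments of Arg-TCT had 1249 reads there and 0 elsewhere. Of 59 tRNA isodecoders with at least 10 reads of 3' fragments ending in CC in the other 6 libraries, 12 had 0 CCA-ended reads there, and all 12 had them in 8-week replicate 4 (4145 reads). The sums of mt-Gly-TCC 3-tRFs and Gly-CCC 3-tRFs had log2 fold changes of 4.46 and 4.35 and did not pass in edgeR. These folds rested largely on 8-week replicate 4, at 1952 and 8157 CPM, against 53.9 to 110 and 100 to 216 in the other 8-week libraries. With 8-week replicates 1 and 4 out, the mt-Gly-TCC 3-tRFs were among the sums called in edgeR. None (0) of the 177 was among the 740 tested fragments, so they enter the sums and shares but no fragment or set test, and without them 0 sums passed in edgeR.

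**Figure D4:**
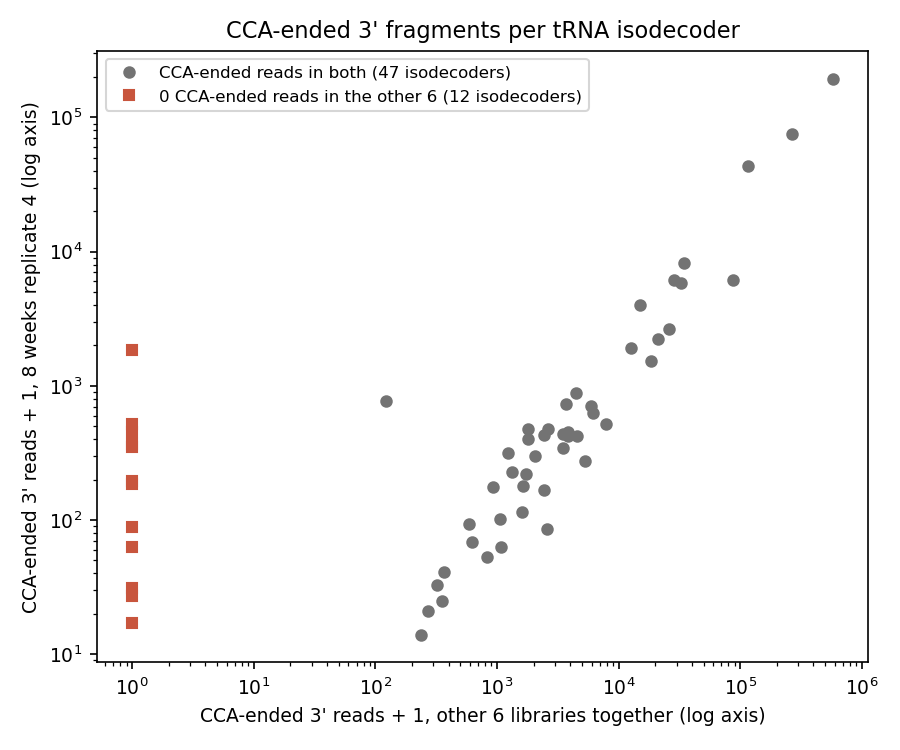
CCA-ended 3' reads per tRNA isodecoder plus 1 in 8-week replicate 4 against the other 6 libraries together (both axes log), 1 point per isodecoder with at least 10 CC-ended reads in those 6. The 12 isodecoders drawn as squares have 0 CCA-ended reads in the other 6 libraries and 4145 in 8-week replicate 4, and 47 have reads in both.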

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

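All tests of explanations in this part were chosen after the results were seen. In the 44 groups of 4 libraries examined for a library far from the others, 4 stood apart, where chance gives about 1 in 20 groups, or 2.2.

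In 8-week replicate 1, the mt-His-GTG 5-tRF 0-51 stood at 270102 CPM (median of the other 8-week libraries 25980) and the mt-Gly-TCC 5-tRF 1-51 at 128222 (11750), and mitochondrial 5-tRFs of 51 and 52 nt made up 29.98% of that library and 4.52% to 6.45% of the other 6, a ratio to their median of 6.00. The rise was not general: of the 7 tRNAs with at least 100 such reads there, mt-His, mt-Gly, mt-Met, mt-Pro and mt-Asp were raised (6.49, 5.97, 4.11, 6.80 and 5.12), mt-Ile was at 1.77 and mt-Ala at 0.684, among those with fewer reads mt-Thr was at 4.01 and mt-Glu, mt-Gln and mt-Arg at 0.548, 0.368 and 0.299, and some longer ends of mt-Asn, mt-Asp and mt-His were raised too (761, 948 and 1051 reads at positions 54, 55 and 55). The rise lay at particular end positions and not at those beside them. For mt-His, position 51 had 43019 reads there and 7979 in 8-week replicate 3, and position 50 had 333 and 1642. For mt-Gly, position 51 had 20313 and 3724, and position 52 had 90 and 650. For mt-Met, position 52 had 7919 and 1521, and position 51 had 149 and 463. A selection of short inserts would raise nuclear 5-tRFs of that length, which were at a ratio of 0.477, and more mitochondrial RNA would raise longer mitochondrial 5-tRFs, which were at 0.597, so both values argue against these as the whole cause. More RNA of the raised tRNAs alone is argued against for mt-His, mt-Gly, mt-Met and mt-Pro, whose longer 5-tRFs were at 0.805 at most, and stays open for mt-Asp, whose longer ones were at 3.86 and 3-tRFs at 1.40. The mt-Asp value of 3.86 rested largely on position 55, at 948 reads. Positions 54 and 56 had 5 and 7 reads there, too few to settle it. A cleavage or ligation that differed in this library may remain, untested here, and the 3 other 8-week libraries of the same age did not show the rise.

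In 8-week replicate 4, 177 fragments with at least 5 reads were at 0 in the other 6 libraries, 154 of them above the highest level that a count of 0 allows in those libraries (15.1 CPM) and the rest, from 12.2 CPM, within the span of those limits. Depth does not account for it, as the deeper 8-week replicate 2 held 51 reads of fragments found that way, against 6853. More RNA of these tRNAs in that library is argued against for 18 of the 29 isodecoders by their other fragments. These were at a median ratio of 0.372 to the other libraries. More RNA stays open for the remaining 11, with under 10 other reads each elsewhere. These 11 had 58 other reads there, against 3.49 that depth gives from the 14 elsewhere. Of the 58 reads, 42 came from 6 isodecoders with no read of any kind in the other 6 libraries. The 11 were grouped by having few reads elsewhere, so an excess there follows in part from the grouping and cannot decide it. A counting of CCA-ended sequences that differed between libraries is a candidate explanation: 12 isodecoders had 480 CC-ended and 0 CCA-ended reads in the other 6 libraries, where 26070 would be expected at the ratio of the other 47 isodecoders. No biological explanation was tested.

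The methionine share was 3.54% in 8-week replicate 1, against a median of 1.10% in the other 8-week libraries. The tyrosine share was 0.245% in 8-week replicate 4, against 0.0222%. The CCA-ended reads of Tyr-GTA-2/3, Tyr-GTA-1 and Tyr-GTA-4 numbered 517, 369 and 64 there and 0 in the other 6 libraries, so this flag is part of the CCA pattern above.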

How the results depend on the processing

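The uses of either constant as library size, the removals of fragments of 8-week replicate 4 alone and of 8-week replicates 1 and 4 together, fry and medians under other scalings, and fry and the DESeq2 Wald test of sums with libraries left out were chosen after seeing the data. Called fragments (1) numbered 0 with DESeq2 size factors, total counts alone, no filter, a mean CPM of at least 10, the first constant, or 8-week replicates 1 and 4 out, 2 at an adjusted p under 0.1 or with the second constant, 4 with the DESeq2 Wald test or nuclear sources alone, and 0 to 0 with 1 library out. Called sums (0) numbered 2 with total counts, 7 with the DESeq2 Wald test, 1 with the second constant, 8 with replicates 1 and 4 out, and 0 to 1 with 1 library out. Called sets (12) numbered 0 with an estimated correlation, 6 with fry, 16 with replicates 1 and 4 out and 8 to 15 with 1 library out. Classes of composition passing (0) numbered 1 with nuclear sources as denominator, mean length, which is alone in its family and so not corrected, and 0 to 0 with 1 library out. Leaving out libraries or fragments changes how much is tested, and otherwise the cause was not tested. Log2 fold changes turned for His-GTG-2 12-75 (−0.094), His-GTG-2 8-75 (−0.34) and Glu-CTC-1 13-75 (−0.080) with total counts, and to −0.12, −0.41 and −0.091 with the second constant. With 8-week replicates 1 and 4 out they turned for His-GTG-2 13-75 (−0.16), 14-75 (−0.26) and 12-75 (−0.21), mt-Gly-TCC 1-51 (−0.075) and Glu-CTC-1 13-75 (−0.0097), and with 1 library out the mt-Gly-TCC 1-51 value ran from −0.054 (without 8-week replicate 1) to 2.24. With 1 library out the share difference ran from −7.94 to 0.598 points for 3-tRFs and from −0.0624 to 8.33 for 5-tRFs, and that of mean length from −0.417 to 0.451 nt, turning without 8-week replicate 1. With nuclear sources as denominator they turned to 1.97, −1.54 and 0.571 nt, and without the 10 most abundant fragments mean length turned to 0.197 nt. Of single results with 1 library out, 217 kept the direction of the test and side of the threshold, 16 lost a call and 4 turned, and under the other settings 299, 27 and 15. Among those not counted as turned, 8 set medians changed sign while the direction of the test, relative to other fragments, did not: mitochondrial and glutamate with total counts (−0.21 and −0.20, the glutamate call ending), mitochondrial, glutamate, alanine and lysine with the second constant (−0.25, −0.24, −0.0023 and −0.0051), and mitochondrial without 4-week replicate 3 (−0.12) or 8-week replicate 3 (−0.0022), where its call ended. The restriction to fragments of a single source and the removal of those of 8-week replicate 4 alone removed no tested fragment. The planned pseudocounts and the test of other small RNAs were not run, since the table gives counts and holds tRNA fragments. No paired analysis was possible because the labels give no replicate numbers. Total counts of 198330 to 431743 per library limit what low fragments can show.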

Other observations

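All tests of explanations in this part were chosen after the results were seen. The counts per tRNA that follow are of overlapping fragments, which are not independent, and differences between the tRNAs of an amino acid were not tested. By edgeR's fitted values, all 16 tested fragments of nuclear Ser-GCT were lower at 8 weeks (median −0.75), in every scaling by median, while 4 of 5 of Ser-TGA were higher (median 0.54, but −0.07 with total counts alone and −0.10 with the second constant, where the log2 CPM medians were 0.12 and 0.09). All 13 of nuclear Asn-GTT were lower, 9 of them at an unadjusted p under 0.05 in edgeR. Arginine fragments were not shifted one way (fry adjusted p = 0.617 in limma). Fry's mixed test, for change in either direction, gave an adjusted p of 0.000757 in limma. It also gave 0.000702 for asparagine, 0.00464 for leucine and 0.0270 for initiator methionine, and is given only for all 7 libraries under the main scaling. All 4 fragments of Arg-TCG were lower and the 2 of mt-Arg-TTC higher, while 9 of Arg-CCG were higher and 8 lower, and 3 of Arg-CCT higher and 3 lower. No arginine fragment passed in edgeR, even adjusted over the list alone (lowest adjusted p = 0.0789). Among mitochondrial tRNAs, all 14 Glu-TTC, all 9 Cys-GCA, 18 of 19 Ala-TGC and 16 of 17 Gln-TTG fragments were higher. Their fitted medians stayed above 0 in the 5 scalings tried, but with the second constant the median on the log2 CPM scale was −0.0021, −0.02, −0.0023 and 0.07. All 6 of mt-Leu-TAG (median −0.58), 9 of 15 of mt-Val-TAC (−0.15) and 17 of 28 of mt-Ile-GAT (−0.05, but 0.02 with DESeq2 size factors) were lower, and over all 227 mitochondrial fragments 163 were higher and 64 lower, against 108 and 119 with total counts alone and 92 and 135 with the second constant.

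The lower leucine and asparagine levels were set against technical trends. Removing a linear trend on GC content and length per library left medians of −0.99 for leucine (SD over members 0.71, from −1.10 with 0.73) and −0.90 for asparagine (0.56, from −0.96 with 0.65), with fry adjusted p values of 0.0412 and 0.0137 in limma, which argues against those trends as the whole cause. For histidine, proline and initiator methionine, fry's call ended after it (adjusted p = 0.140, 0.216 and 0.249 in limma), the medians going from 0.51 to 0.47, −0.41 to −0.36 and −0.86 to −0.76, and the medians of the mitochondrial and alanine fragments, which fry did not call, went from 0.27 to 0.08 and from 0.50 to 0.26. Lysine kept fry's call after the removal (adjusted p = 0.0256 in limma), its median going from 0.50 to 0.52. Without 4-week replicate 3 and 8-week replicate 1, in which the second constant was the smallest part of the first, the set differences were −0.97 and −0.90, against −1.07 and −0.82 with all libraries, which argues against those libraries as the cause. Age, the cells that enter the islets and their share remain open and untested.

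The libraries were also split in all 35 ways into 3 and 4. For fragments, 2 of 35 splits gave as many calls as the real one (1), so chance cannot be excluded, and the highest other gave 9. That split, 4-week replicates 1 and 2 with 8-week replicate 3 against the rest, was picked out after the counts were seen. Whether it reflects a structure of the samples other than age was not tested. For sets with the preset correlation, 8 of 35 gave at least the real 12 (highest other 15, median of the others 10), so chance cannot be excluded. For sums, and for sets with an estimated correlation, the real count was 0 (highest other 2 for each), which any split reaches (35 of 35), so nothing follows for chance. With fry, the real split alone gave 6 (1 of 35, highest other 1), a share of 0.0286 that is the smallest the design allows and is under 0.05 only when taken alone. Adjusted over the 5 comparisons of this kind it was 0.143, so chance cannot be excluded. With total counts alone or the first constant fry called 0 sets, with the second constant 8, and with any 1 library left out 0 or 1.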
